A study of Homo sapiens with 5 samples.

How the data were processed

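Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 histone marks in neural progenitor cells. The cells were derived from H1, an established human embryonic stem cell line. H3K4me3 is trimethylation of lysine 4 of histone H3 and marks the start sites of genes that are active or poised. H3K27me3 is trimethylation of lysine 27, the mark laid down by Polycomb repressive complex 2. Each mark was measured in wild-type cells and in cells in which E2A, the transcription factor encoded by TCF3, had been knocked out with CRISPR-Cas9. The series holds 5 libraries, 1 for each combination of mark and genotype and 1 of input DNA. The input has no track in the files used here. Groups were taken from the submitters' labels.

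The deposited tracks give, for each of the 4 immunoprecipitated libraries, the intervals the authors called, and the track names state 75 bp reads and build hg38. The submitters' processing notes name CASAVA 1.4, BWA, MACS2 and SICER and build GRCh38, without the role of each. The settings of the callers are not given in the sources used here. Every interval is a run of whole 200 bp windows, and neighbouring intervals of 1 library lie at least 800 bp apart. The deposited merged regions number 33269, and all 33269 equal the union of the 4 interval tracks. Coordinates were converted to positions counted from 1. All intervals lie on chromosomes 1 to 22, X and Y.

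Each interval also has a summit value, a whole-number score that the authors deposited for its highest point, from 6 to 368 over the 4 libraries. How the authors normalized this score is not given in the sources used here. The number of reads per library is not in these files either, so the depth behind each interval is unknown and no counting interval or detection floor was calculated. With 1 library per group there are no replicates, so no p-value or standard error was calculated, and a difference between genotypes is a difference between 2 libraries.

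The main comparison of genotypes used the called sets. An interval counted as shared if it overlapped an interval of the other genotype by at least 1 bp. Intervals of both genotypes were also joined into regions where they overlapped. In regions with an interval in each library, the log2 ratio of the higher summit values, knockout over wild type, was calculated after scaling the knockout values so that both libraries had the same total over these regions, with a pseudocount of 1. The factor was 1.02 for H3K4me3 and 1.09 for H3K27me3. Because of this scaling, a ratio places a region relative to the other shared regions of the same 2 libraries and says nothing about absolute amounts of a mark. A size limit of 2-fold was used for counts.

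Gene positions came from the RefSeq table of assembly GRCh38.p14, with 20037 protein-coding genes on these chromosomes. This table has neither strand nor transcript starts. A gene was therefore called marked if an interval lay within 2 kb of either annotated end of the gene, in place of the planned window around transcript starts. Of genes longer than 20 kb with H3K4me3 at an end, 90.0% in the wild type and 90.3% in the knockout had it at 1 end alone.

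Before the data were examined, 21 gene lists with 379 entries were fixed. All 379 entries were found in the gene table, 1 of them, TDGF1, under its newer symbol CRIPTO. A list's share of marked genes was placed among 10000 random lists of the same size. A list's median log2 ratio was placed among 10000 random lists matched on summit level in 10 strata. These percentiles describe these libraries and are not tests over replicates. The overlap of the marks was compared with 1000 random placements in which all H3K27me3 intervals of a chromosome were shifted by a random distance around it.

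Genes were named by a rule fixed in advance. TCF3 was always named. For each mark, the 10 regions at gene ends with the highest and the 10 with the lowest ratio were taken from regions above the median level, at gene ends in place of transcript starts. The 10 widest regions in 1 genotype alone, which the rule gave only for data without ratios, were added once the data were known. From each list, up to 4 genes with the largest ratio in either direction could be named. Genes at the same region were named together. Not every item the rule gives is printed. Genes outside this rule are said to have been chosen after their values were seen.

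Ratios were also summarised in bins of 5 Mb with at least 10 shared regions. A bin was called shifted if its H3K4me3 median lay more than 3.5 robust standard deviations from the centre of all bins, and neighbouring bins beyond 2 robust standard deviations in the same direction were joined to it. Bins with fewer than 10 regions were passed over in joining, so a segment can span them. A segment was kept for the alternatives without segments if H3K27me3 lay on the other side of its centre by over 1 robust standard deviation in its median bin, and this rule was set after the values along the chromosomes had been seen. Alternatives covered the threshold and merging of intervals, the overlap rule, equal numbers of intervals per genotype, the scaling, the pseudocount, the size limit, the gene window and the matching of the random lists. Calculations were done in Python 3.11.15 with NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.

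The procedures were tested on simulated data. For intervals and regions, the wild-type intervals of each mark were copied, intervals were dropped or added, and summit values were raised or lowered. For gene lists, a shift was planted in random values from a normal distribution. All planted intervals, regions and list shifts were found, and no unchanged region passed the size limit. The copied intervals carried no random difference between libraries, and the planted list shift was larger than any list median given below. These tests therefore check the calculations and do not measure false calls in these data.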

Results

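H3K4me3 and H3K27me3 were mapped by ChIP-seq in neural progenitor cells derived from H1 human embryonic stem cells, in wild-type cells and in cells that lacked E2A. E2A is a basic helix-loop-helix factor that pairs with proneural and myogenic factors and is held inactive by the ID proteins. The design compares the genotypes for each mark and sets the marks beside each other. There was 1 library for each mark and genotype and no replicate, so every difference given here is one between 2 libraries and no p-value was calculated. Sequencing depth is unknown, since the files give no read counts.

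TCF3, the gene that encodes E2A, lies on chromosome 19 from 1609292 to 1652615 (hg38). It carried an H3K4me3 interval of 3.8 kb in the wild type and 4.6 kb in the knockout, with a summit value of 203 in each, and no H3K27me3 interval in either. The edited part of the gene is not given in the labels, and an H3K4me3 interval at the gene's end checks nothing about the edit. The genotypes are therefore those of the labels.

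H3K4me3 formed narrow intervals and H3K27me3 broad ones. In the wild type, 24253 H3K4me3 intervals with a median width of 2.6 kb covered 73.0 Mb, and 15552 H3K27me3 intervals with a median width of 5.8 kb covered 124 Mb. In the knockout, 23273 H3K4me3 intervals covered 67.8 Mb and 18691 H3K27me3 intervals covered 149 Mb, at the same median widths. H3K4me3 thus covered less sequence in the knockout library and H3K27me3 covered more. The median summit value was 132 in the wild type and 135 in the knockout for H3K4me3, and 23 and 17 for H3K27me3.

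H3K4me3 in the knockout against the wild type. The pluripotency gene ZFP42, also called REX1, had a strong H3K4me3 interval of 5.4 kb in the knockout alone, with a summit value of 174. HOXB2 and HOXB3, which pattern the hindbrain, had an interval of 6.6 kb in the wild type alone, with a summit value of 76. LRRC4C, which encodes a netrin-G ligand, had 5.8 kb in the knockout alone with a summit value of 50. In the wild type alone lay intervals at ARHGEF38 (6.8 kb), RAB17 (4.8 kb, summit value 80), FOXS1 and DUSP15 (4.6 kb), the midbrain homeobox gene DMBX1 (4.0 kb), XYLT2 (4.0 kb), the initiator caspase gene CASP8 (3.8 kb) and the glycosyltransferase gene MGAT1 (3.8 kb).

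Most H3K4me3 intervals were called in both genotypes. In the wild type, 2166 of 24253 intervals (8.93%) had no overlapping interval in the knockout. In the knockout, 1142 of 23273 (4.91%) had none in the wild type. These intervals were weak, with median summit values of 21 and 20, against 145 and 142 for shared intervals. With equal numbers of the highest summits taken from each genotype, 1584 were in the wild type alone and 1520 in the knockout alone.

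In the 21942 H3K4me3 regions called in both genotypes, summit values were close after scaling to equal totals. A ratio places a region relative to the other shared regions and gives no absolute change. The standard deviation of the log2 ratio was 0.12 above the median level and 0.38 below it. At the 2-fold limit 81 regions were higher in the knockout and 196 lower, and all but 1 of these lay below the median level. The exception was PCDHB5, a clustered protocadherin gene of neuronal cell adhesion, at chromosome 5 from 141134201 to 141136800. Its summit value was 225 in the wild type and 103 in the knockout, 2.14-fold lower. The next lowest ratios at strong regions were smaller than 2-fold. They belonged to NUP107 and SLC35E3 (1.63-fold lower), CRIP1 and TEDC1 (1.62-fold), ZNF441 (1.57-fold), the nucleotide pool enzyme DCTPP1 (1.55-fold), TNFSF9 (1.49-fold), MBD3L1 (1.49-fold), the mitotic kinase gene NEK9 (1.47-fold), HES4, a hairy-related gene (1.47-fold), and PXMP4 (1.47-fold).

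The strong H3K4me3 regions with the highest ratios were likewise below 2-fold. The histone genes H2AC25 and H2BC26 shared a region that was 1.79-fold higher in the knockout, with summit values of 105 and 186. ZNF585B was 1.69-fold higher and GGCT 1.64-fold. ASTN1, which encodes the neuronal migration protein astrotactin, had summit values of 121 and 179, and CHCHD5 of 131 and 181. TBC1D1 was 1.37-fold higher, PREX2 1.35-fold, POGK 1.34-fold and COLGALT2 1.34-fold. ASTN1, POGK and COLGALT2 lie in a segment of chromosome 1 in which the H3K4me3 median was higher, and PXMP4, FOXS1 and DUSP15 in a segment of chromosome 20 in which it was lower. Without these segments 74 regions were higher and 191 lower at the 2-fold limit.

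HOX genes carried less H3K4me3 in the knockout library while their H3K27me3 was nearly the same. HOX genes set position along the body axis, and in the nervous system they are used in the hindbrain and spinal cord. Of 39 HOX genes, 28 had H3K4me3 in the wild type and 19 in the knockout. HOXB2, HOXB3, HOXB4, HOXC4, HOXC5, HOXC6, HOXC11, HOXD10 and HOXD12 had it in the wild type alone, and 0 had it in the knockout alone. These 9 genes, named after their values were seen, rest on 6 separate wild-type intervals, since HOXB2 and HOXB3 share 1 and HOXC4, HOXC5 and HOXC6 share another. H3K4me3 covered 61.7 kb of the 4 clusters in the wild type and 35.6 kb in the knockout. The covered length was 10.2 against 1.56 kb in HOXB, 6.37 against 0.97 kb in HOXC, 26.0 against 16.8 kb in HOXD and 19.1 against 16.3 kb in HOXA. H3K27me3 covered 100% of each cluster in both genotypes. The direction for H3K4me3 rests on the genotype labels of that mark. With these labels exchanged, 19 HOX genes would have H3K4me3 in the wild type and 28 in the knockout.

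**Figure D1:**
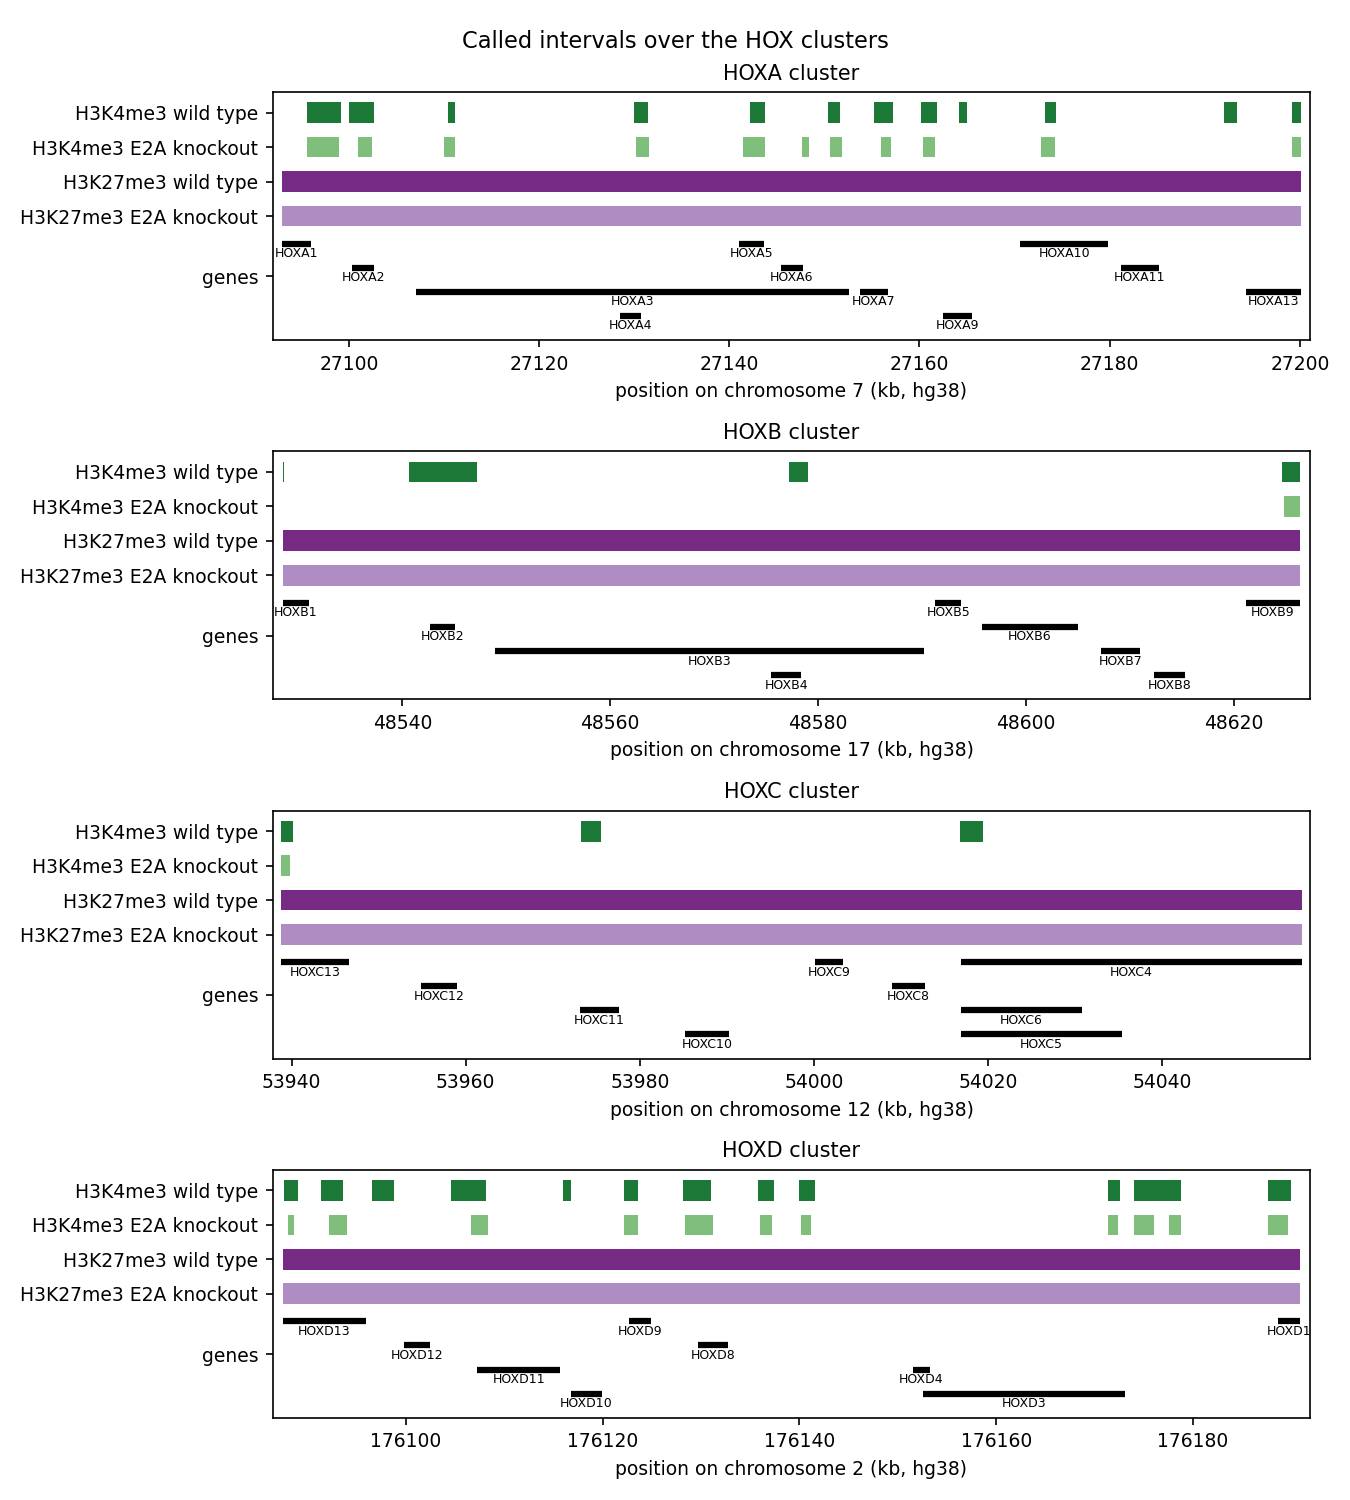
Called intervals over the HOX clusters A to D, with position in kb (hg38) on the horizontal axis, a row of bars for each library and the genes as black lines in staggered rows. H3K27me3 spans each cluster in both libraries, and H3K4me3 is called in 31 intervals in the wild type and 24 in the knockout.

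The HOX genes with H3K4me3 in both libraries also had lower summit values in the knockout. The median log2 ratio of 19 genes was -0.44, below all 10000 random lists of like summit level, of which 95% had medians between -0.22 and 0.12. The 19 genes shared 16 separate regions, of which 14 had a ratio below 0, with a median of -0.43. The region at HOXA3 had summit values of 41 and 19 (2.07-fold lower), while the intervals nearest to HOXA7, whose ratio was taken from that region, had 37 and 22. HOXC13 had summit values of 38 and 18 (2.02-fold lower) and HOXB9 of 50 and 29 (1.67-fold lower). For H3K27me3 the 39 HOX genes lay in 5 regions, with ratios between -0.09 and -0.06. HOX intervals of H3K4me3 are weak, and 0 HOX genes kept an interval in either genotype when only summit values at or above each library's median were used.

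Neural progenitor markers had slightly higher H3K4me3 summit values in the knockout. Of 21 markers with a ratio, 16 lay above 0 and 5 below, with a median of 0.11 at the 99.6th percentile of random lists. PAX6, a master regulator of neuroectoderm and eye, was 1.25-fold higher with summit values of 86 and 106. The cortical selector gene LHX2 was 1.24-fold higher and ZBTB16 1.24-fold higher, while ZIC1 went the other way at 1.25-fold lower. The other lists lay within the middle 95% of random lists for H3K4me3. Forebrain regulators had a median of 0.00, with NKX2-1 1.70-fold lower (68 and 39) and GSX2 1.35-fold higher. Midbrain, hindbrain and spinal cord regulators had a median of -0.04, with LMX1A, which lies in the chromosome 1 segment, higher (112 and 154) and LMX1B 1.31-fold lower. Neurogenic transcription factors had a median of -0.07, with NEUROG1 1.57-fold and NEUROD4 1.52-fold lower and TLX3 higher (44 and 61). Neuronal genes had a median of -0.05, with ELAVL4 1.76-fold higher (40 and 70) and DCX 1.46-fold lower.

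Among genes of other cell types, pluripotency genes had a median H3K4me3 ratio of -0.02, with NANOG 1.61-fold lower (40 and 24) and TERF1 1.25-fold higher. Glial genes had a median of -0.03, with SOX10 1.53-fold higher (67 and 101). The medians were -0.06 for mesendoderm genes, with EVX1 1.65-fold lower, -0.01 for neural crest genes, -0.07 for surface ectoderm genes, with GRHL3 1.26-fold lower, and -0.00 for blood genes and for muscle and liver genes. For signalling they were 0.01 for the NODAL and TGF-beta pathway, 0.05 for the BMP pathway, 0.04 for the WNT pathway and -0.06 for the NOTCH pathway, with DLL3 1.34-fold lower. They were 0.02 for E proteins and inhibitors of DNA binding, -0.01 for cell cycle regulators, 0.07 for Polycomb and trithorax enzymes and 0.05 for housekeeping genes. Among 41 list medians over both marks, 5 lay outside the middle 95% of random lists, where chance gives 2.05.

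**Figure D2:**
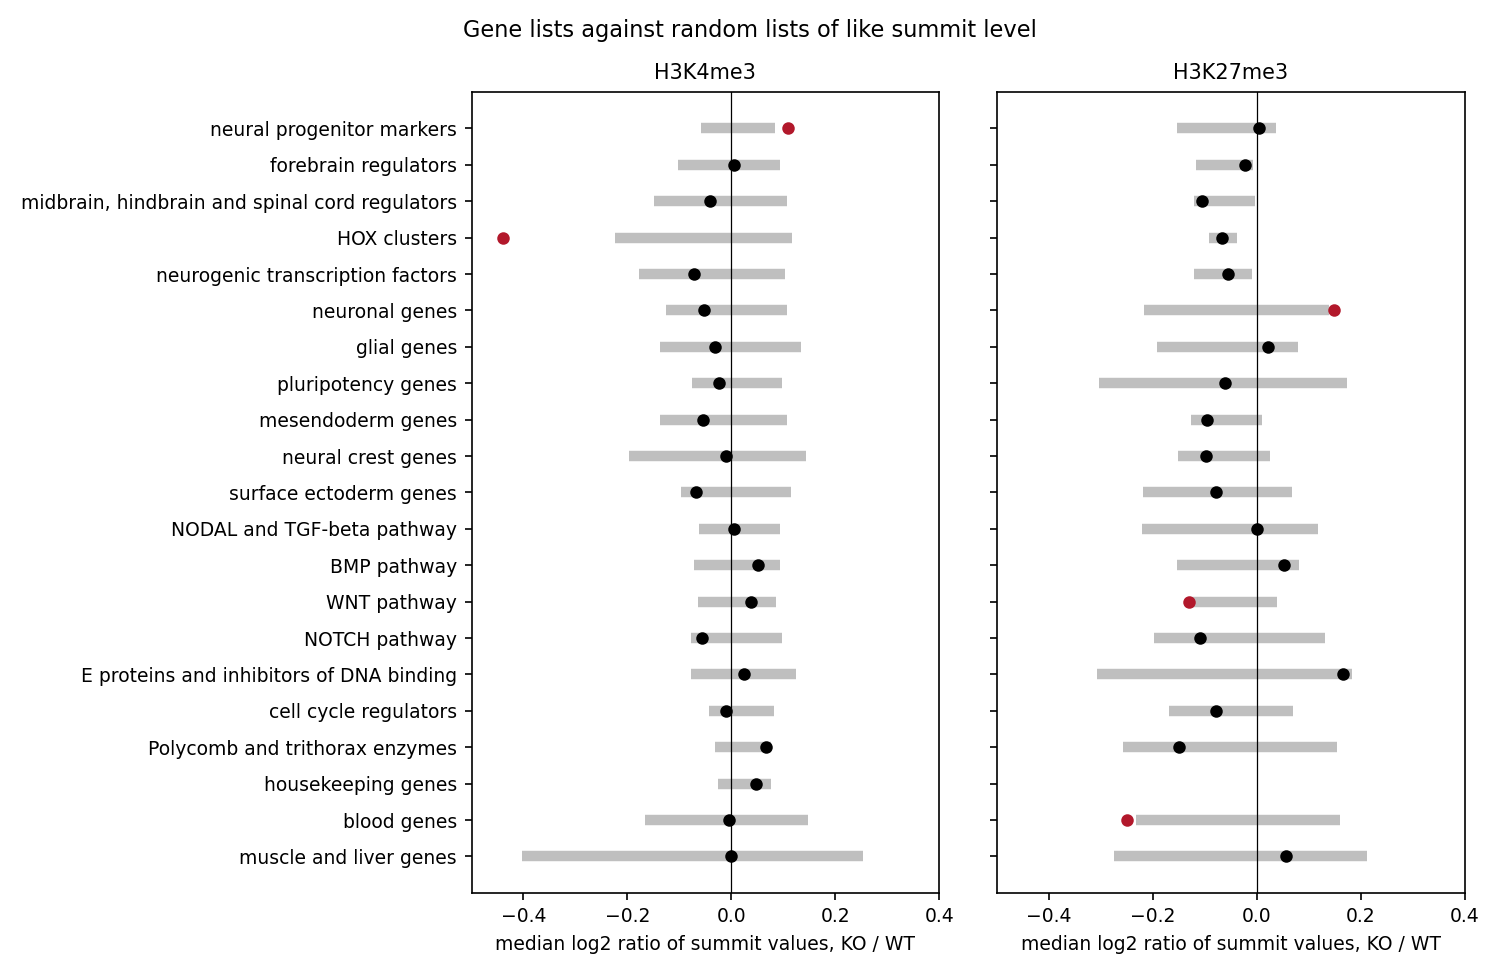
Median log2 ratio of summit values, knockout (KO) over wild type (WT), for each gene list (points; red if outside the range) and the middle 95% of 10000 random lists of like summit level (grey bars), for H3K4me3 on the left and H3K27me3 on the right. The HOX clusters stand farthest from their range, at -0.44 for H3K4me3, and housekeeping genes have too few H3K27me3 regions for a median.

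H3K27me3 in the knockout against the wild type. SCRT2, which encodes a zinc finger repressor of the nervous system, was 7.03-fold lower with summit values of 90 and 11. CCK, which encodes the neuropeptide cholecystokinin, was 5.18-fold lower with 83 and 14, and its covered length was 15.0 kb in the wild type and 3.0 kb in the knockout. The other lowest ratios were at PTGDS, LCNL1, PAXX and CLIC3 (4.57-fold lower), KBTBD12 (4.41-fold), the carboxylesterase gene CES2 (3.99-fold), the unnamed gene LOC107987432 (3.97-fold), TRIM15 (3.83-fold), the kallikrein gene KLK4 (3.47-fold), GPR132 (3.44-fold) and CLEC3B (3.37-fold).

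The highest H3K27me3 ratio was at ACOT4, an acyl-CoA thioesterase gene, which was 3.41-fold higher in the knockout with summit values of 13 and 43. DNAH8, a dynein heavy chain gene, was 3.19-fold higher. PHACTR3 was 2.66-fold higher, and its covered length was 16.4 kb in the wild type and 62.8 kb in the knockout. CDX4, a caudal homeobox gene upstream of HOX genes, was 2.59-fold higher, TMEM121 2.24-fold, BMP2 2.17-fold, MMP24 2.13-fold and TEX19 2.04-fold. The cell cycle factor gene E2F1 (2.33-fold) and ID1 (2.05-fold) were also higher. With a pseudocount of 10, E2F1, TMEM121, BMP2, MMP24, ID1 and TEX19 fell below 2-fold, and ID1 and TEX19 did so with median ratio scaling. ID1 encodes an inhibitor of E proteins, and the H3K27me3 region at its end covered 19.8 kb in the wild type and 36.2 kb in the knockout. E2F1 and ID1 lie in the chromosome 20 segment, in which the H3K27me3 median was higher. The MMP24 region starts at 35223201, just beyond the end of that segment at 35 Mb, which the 5 Mb bins set.

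The widest H3K27me3 regions of 1 genotype alone were mostly regions of the knockout. They lay at BPIFB1 (28.0 kb), the olfactory receptor genes OR1J4 and OR1N1 (27.8 kb), CEACAM7 (22.6 kb), EIF6, FAM83C and UQCC1 (22.6 kb), BPIFA2 (21.4 kb), the defensin genes DEFB126 and DEFB127 (21.0 kb), OR1N2 (18.6 kb) and SUN5 and BPIFB2 (16.6 kb). BPIFB1, BPIFA2, SUN5 and BPIFB2 lie in the chromosome 20 segment, and the region of EIF6, FAM83C and UQCC1 starts just beyond its end, at 35284401. In the wild type alone lay MPZL3 and MPZL2 (18.8 kb) and the keratin gene KRT10 (16.2 kb). Apart from OR1N2 at 40, the knockout regions were weak, with summit values from 14 to 26, where the median of that library was 17. The wild-type regions had 37 and 23, where the median was 23.

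The knockout library had more H3K27me3 intervals without a partner. In the wild type, 2114 of 15552 intervals (13.6%) had no overlapping interval in the knockout, and 5240 of 18691 (28.0%) in the knockout had none in the wild type. These intervals were weak, with median summit values of 14 and 11 against 27 and 25 for shared ones. With equal numbers of the highest summits, 2798 were in the wild type alone and 2961 in the knockout alone. In 12475 regions called in both, the standard deviation of the log2 ratio was 0.38. At the 2-fold limit 80 were higher and 119 lower, and 26 and 84 of these lay above the median level. At 1.5-fold the balance turned, with 904 higher and 583 lower. Without scaling, the median of all regions moved from 0.04 to -0.08, and 50 were higher and 184 lower. Without the segments of chromosomes 1 and 20, 77 were higher and 109 lower.

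Gene lists differed little in H3K27me3. The median ratio of 11 neuronal genes was 0.15, at the 98.4th percentile of random lists, but the list was split, with 6 genes above 0 and 5 below. Among those below were ELAVL4 at 2.29-fold lower (61 and 24) and the neurofilament gene NEFM at 1.59-fold lower. The WNT pathway had a median of -0.13 at the 2.46th percentile, with 15 of 17 genes below 0, among them AXIN2 (1.42-fold lower) and SFRP2 (1.33-fold lower). Blood genes had a median of -0.25 at the 1.97th percentile, with CD3E 1.76-fold lower. Each of these 3 percentiles came back within the middle 95% with another gene window, and that of blood genes also without the segments of chromosomes 1 and 20, with medians of 0.07 for neuronal genes at 5 kb, and of -0.12 for the WNT pathway and -0.21 for blood genes at 1 kb. Without scaling, the medians of neural progenitor markers, glial genes, the NODAL and TGF-beta pathway, the BMP pathway and muscle and liver genes lay below 0 for H3K27me3, at -0.11, -0.10, -0.12, -0.07 and -0.06.

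Other lists lay within the range of random lists for H3K27me3. E proteins and inhibitors of DNA binding had a median of 0.16 over 6 genes, with ID1 2.05-fold and ID3 1.34-fold higher and TCF12 1.34-fold lower. Polycomb and trithorax enzymes had a median of -0.15, with the H3K27 demethylase gene KDM6B 2.14-fold lower (87 and 37) and KDM5B, in the chromosome 1 segment, 1.85-fold lower. The NOTCH pathway had -0.11, with DLL1 1.43-fold lower (106 and 68), and cell cycle regulators -0.08, with CDKN1A 1.75-fold and CCND1 1.57-fold lower. The BMP pathway had 0.05, with BMP2 2.17-fold and NOG 1.32-fold higher, and the NODAL and TGF-beta pathway 0.00, with LEFTY2 1.96-fold higher. Medians were 0.00 for neural progenitor markers, -0.02 for forebrain regulators, with LHX5 1.53-fold lower, and -0.11 for midbrain, hindbrain and spinal cord regulators. They were -0.06 for neurogenic transcription factors, with MYT1 2.29-fold lower (46 and 18), and -0.07 for the HOX clusters. They were 0.02 for glial genes, -0.06 for pluripotency genes, -0.10 for mesendoderm genes and for neural crest genes, -0.08 for surface ectoderm genes and 0.06 for muscle and liver genes, with DES, the desmin gene, 3.25-fold lower (80 and 22).

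All 17 midbrain, hindbrain and spinal cord regulators and all 20 neurogenic transcription factors carried H3K4me3 and H3K27me3 in both genotypes, and forebrain regulators did so in 19 of 19 genes in the wild type and 18 of 19 in the knockout, where no H3K27me3 interval was called at HESX1 (a weak one, with a summit value of 20, in the wild type). Housekeeping genes had H3K4me3 in 20 of 20 and H3K27me3 in 2 in the wild type and 1 in the knockout. Muscle and liver genes had H3K4me3 in 5 of 15 genes in the wild type and 6 in the knockout. H3K27me3 marked 15 of the 21 lists more often than the middle 95% of random lists in the wild type, and H3K4me3 marked 11. With lists matched on gene length these were 15 and 9, without the WNT pathway and the Polycomb and trithorax enzymes for H3K4me3.

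Over all 20037 protein-coding genes, 8082 had H3K4me3 alone in the wild type, 6725 both marks, 623 H3K27me3 alone and 4607 neither. In the knockout these were 8468, 6315, 807 and 4447. With the H3K27me3 labels exchanged, genes with both marks would number 6335 in the wild type and 6741 in the knockout. The state was the same in both genotypes for 18369 genes. The most frequent difference, in 693 genes, was both marks in the wild type and H3K4me3 alone in the knockout. The reverse was found in 301 genes. These directions pair the marks by their labels, and with the H3K27me3 labels exchanged the numbers would be 301 and 693. Among list members, NOTCH1, HESX1, JAG1, CCND1, TUBB3, SLC1A3, NANOG, GRHL2, WDR5, EED and RPS3 had H3K27me3 in the wild type alone, and MYC, CTNNB1, SFRP1 and RBFOX3 in the knockout alone, all with H3K4me3 in both genotypes. At CCND1, SLC1A3, RPS3, WDR5 and SFRP1 the other genotype also had an H3K27me3 interval in the same region, but farther than 2 kb from the gene ends. These genes were chosen after their values were seen. Several of the intervals were weak, against median H3K27me3 summit values of 23 in the wild type and 17 in the knockout. In the wild type the values were 16 at NANOG, 18 at JAG1 and 20 at HESX1 and GRHL2, but 43 at TUBB3. In the knockout they were 10 at RBFOX3 and 14 at CTNNB1. With summit values at or above the median of each library alone, the order of the 2 changes turned, with 299 genes from both marks to H3K4me3 alone and 379 the other way.

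**Figure D3:**
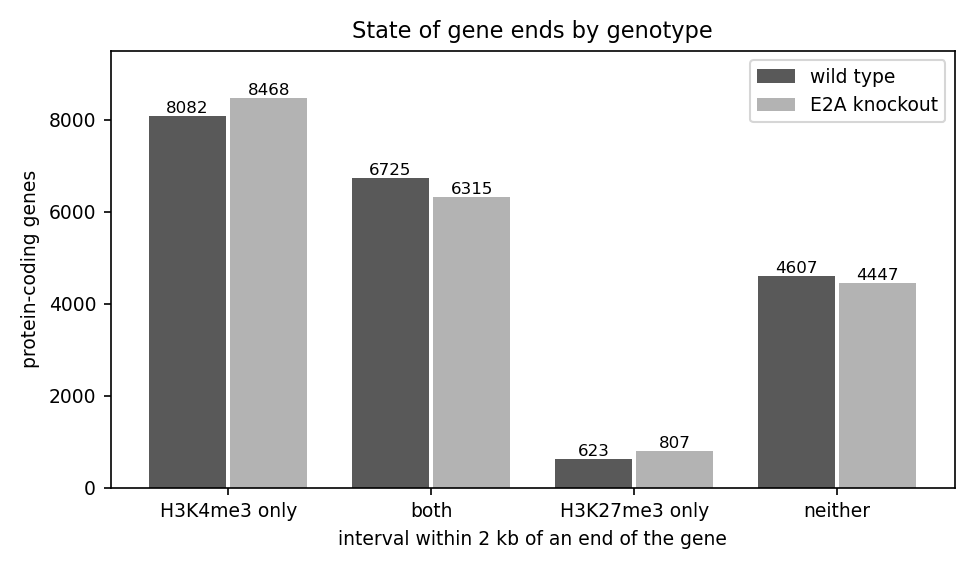
Number of protein-coding genes (vertical axis) with H3K4me3 alone, both marks, H3K27me3 alone or neither within 2 kb of an annotated end, in wild-type (dark bars) and knockout libraries (light bars). Genes with both marks number 6725 in the wild type and 6315 in the knockout as labelled, and would number 6335 and 6741 with the H3K27me3 labels exchanged.

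The marks overlapped more often than randomly placed intervals. In the wild type, 10565 of 24253 H3K4me3 intervals (43.6%) overlapped H3K27me3, against a mean of 1504 and a highest value of 1754 over 1000 random placements. In the knockout, 9920 of 23273 (42.6%) did, against a mean of 1687 and a highest value of 1910. The shared sequence was 26.0 Mb in the wild type and 23.2 Mb in the knockout. Of H3K27me3 intervals, 59.1% overlapped H3K4me3 in the wild type and 46.7% in the knockout. These values pair the marks by their labels. With the H3K27me3 labels exchanged, H3K4me3 of the wild type would share 24.0 Mb with H3K27me3 and that of the knockout 25.3 Mb, and 47.3% and 59.7% of H3K27me3 intervals would overlap them. Random placement takes no account of the tendency of both marks to lie at genes.

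On chromosome 1 from 145 to 210 Mb, the H3K4me3 median was higher and the H3K27me3 median lower in the knockout library. The median log2 ratio of 673 shared H3K4me3 regions was 0.18 against -0.01 elsewhere, and that of 331 shared H3K27me3 regions was -0.15 against 0.04. Both lay outside the range of the other windows of this length, -0.04 to 0.06 for H3K4me3 and -0.04 to 0.14 for H3K27me3. For H3K4me3 this follows from how the segment was picked and is no separate support. The segment was also kept only because H3K27me3 lay on the other side. The other windows overlap each other, and chromosomes shorter than the segment, such as chromosome 19, gave none. In the bins from 175 to 180 Mb and from 185 to 190 Mb the H3K27me3 median lay above 0, at 0.04 and 0.06. H3K4me3 intervals of the segment were in the wild type alone in 28 cases and in the knockout alone in 70. For H3K27me3 these numbers were 135 and 59. On chromosome 20 from 30 to 35 Mb the marks shifted the other way, with a median of -0.21 for 73 H3K4me3 regions and 0.33 for 34 H3K27me3 regions. The H3K4me3 value lay below all other windows of this length, which its picking by H3K4me3 favours. The highest H3K27me3 median of another window was 0.39. Of 4 segments shifted in H3K4me3, the others lay on chromosome 4 from 20 to 25 Mb, with medians of 0.20 for 12 H3K4me3 regions and 0.19 for 11 H3K27me3 regions, and on chromosome 6 from 100 to 105 Mb, with -0.18 for 15 and 0.00 for 5. The rule for these segments was set after the values along the chromosomes had been seen.

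**Figure D4:**
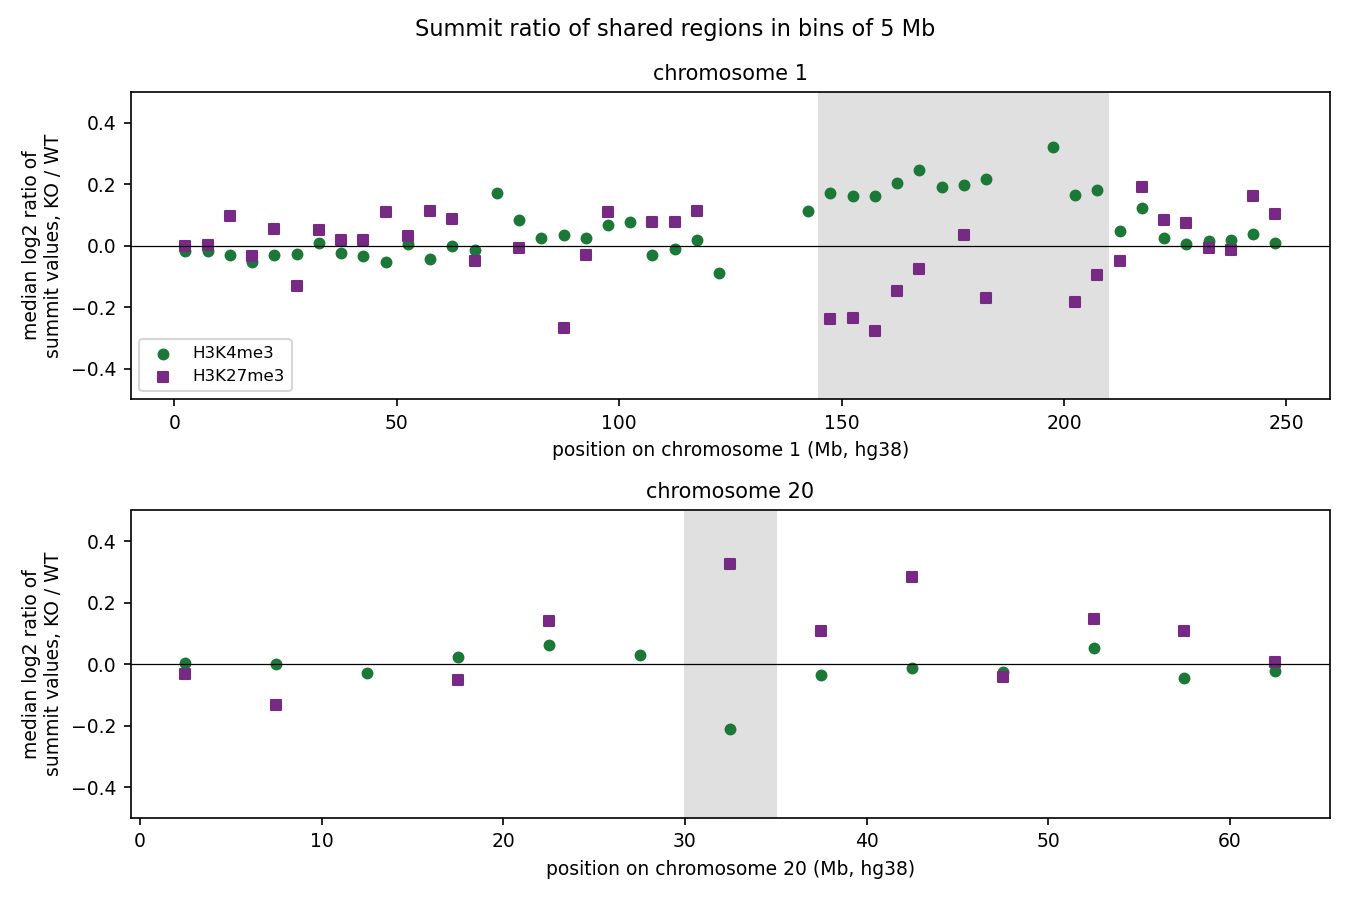
Median log2 ratio of summit values, knockout (KO) over wild type (WT), of shared regions in bins of 5 Mb with at least 10 regions (points) along chromosomes 1 and 20 (position in Mb, hg38), for H3K4me3 (circles) and H3K27me3 (squares), with the shifted segments in grey. From 145 to 210 Mb on chromosome 1 the H3K4me3 bins lie above 0, and at 30 to 35 Mb on chromosome 20 the marks lie at -0.21 and 0.33.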

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

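The tests of contrast between strong and weak regions, of the caudal regulators, of copy number in both segments and of exchanged labels were chosen only after the results were seen. The marks differed in direction in the values given here, and the differences themselves were not tested, because each group has 1 library.

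The covered length went opposite ways in the marks, with a log2 ratio of knockout over wild type of -0.106 for H3K4me3 and 0.258 for H3K27me3. Calls of weak enrichment near the calling limit are a candidate explanation for the extra H3K27me3 intervals of the knockout, since at a summit value of 23 or more, the wild-type median, 95 intervals lay in the knockout alone and 325 in the wild type alone, a ratio of 0.292. With each library's own median as the limit the excess stayed, at 2308 against 543, but that limit is lower in the knockout. The ratio of shared H3K27me3 regions above the median level lay below that of weaker ones, with a difference of -0.123, so a lower contrast in that library and a spread of weak H3K27me3 in cells without E2A cannot be told apart with 1 library per genotype.

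H3K4me3 summit values at the HOX clusters were lower in the knockout library. A loss of height shared by all weak regions is argued against by the HOX median, at percentile 0 of random lists of like summit level. Fewer copies of the segments that hold the clusters are argued against by 272 shared regions within 2 Mb outside them, with a median of -0.076 against -0.44 for the HOX genes. A general shift shared by midbrain, hindbrain and spinal cord regulators is argued against by their list, at percentile 34.59. That list mixes midbrain genes with more caudal ones and holds no CDX gene, so it cannot decide on a shift of posterior genes alone. Whether the loss of E2A or another difference between these cultures goes with the lower HOX values was not tested. With the H3K4me3 labels exchanged, the HOX values would be higher in the knockout.

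Of 4 segments picked out by H3K4me3, those of chromosomes 1 and 20 shifted in opposite ways in the marks, while on chromosome 4 both medians lay above 0 (0.20 and 0.19), for H3K27me3 within the range of other windows. Relative to the rest of the genome, the median log2 ratio differed by 0.188 for H3K4me3 and -0.188 for H3K27me3 in the chromosome 1 segment, and by -0.206 and 0.286 in the chromosome 20 segment. Gains of parts of these chromosomes recur in cultured human pluripotent stem cells. A difference in copy number, with all labels right and both marks from the same cultures, would shift both marks the same way. This is argued against in the chromosome 1 segment, as picked out by H3K4me3 alone. Its H3K27me3 median of -0.15 lay below the lowest of 306 other windows, -0.04. These windows overlap each other, and chromosomes shorter than the segment, such as chromosome 19, gave none. On chromosome 19 the H3K27me3 medians of bins with at least 10 regions ran from -0.16 to 0.16. In the chromosome 20 segment the H3K27me3 median of 0.33 lay within the range of other windows, up to 0.39. That comparison alone cannot tell. Fewer copies would lower H3K27me3 there, yet 82.4% of its 34 regions lay above the median elsewhere. With the H3K4me3 difference taken off, the median was 0.53, while the other windows were not adjusted. That difference was picked for its size, and the segment was kept only because H3K27me3 lay on the other side. Neither value therefore decides, and copy number stays open on chromosome 20. Exchanged genotype labels of 1 mark could bring the shifts into the same direction, and 20.339% of 118 overlapping region pairs outside the segments that changed by 0.5 or more in both marks changed the same way, which argues against an exchange only if the marks oppose each other. Exchanged labels, separate cultures for each mark and a coordinated change of chromatin therefore cannot be told apart, and the direction given for 1 of the marks stays open with them.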

How the results depend on the processing

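Segments left out, the absence of scaling, intervals anywhere in the gene and lists matched on gene length were chosen after seeing the data, and the other alternatives before the data were examined. With summit values at or above each library's median, which removes intervals by construction, 12131 and 11678 H3K4me3 intervals and 8007 and 9919 H3K27me3 intervals remained in wild type and knockout. Then 796 and 336 H3K4me3 and 543 and 2308 H3K27me3 intervals were in wild type or knockout alone, 3683 and 3591 genes had both marks, 299 genes went from both marks to H3K4me3 alone, 3772 and 3644 H3K4me3 intervals overlapped H3K27me3, and 0 and 0 HOX genes had H3K4me3. With equal numbers of the highest summits, 2961 H3K27me3 intervals were in the knockout alone. For regions higher and lower in the knockout, a 1.5-fold limit gave 365 and 876 for H3K4me3 and 904 and 583 for H3K27me3, and a 4-fold limit 5 and 9, and 0 and 6. At 1.5-fold the balance for H3K27me3 thus turned towards higher. Regions above the median level gave 0 and 1 for H3K4me3 and 26 higher for H3K27me3. A pseudocount of 10 gave 36 and 99, and 16 and 49. Without scaling H3K27me3 gave 50 and 184. Where the construction of an alternative does not show it, the cause was not tested. Counts stayed within 1.5 times for called intervals when those closer than 1 kb were merged, for intervals in 1 genotype alone and overlaps of the marks at 50% of the shorter interval, and for regions past the 2-fold limit with median ratio scaling or a pseudocount of 0.1. The same held for genes with both marks, their 2 changes of state and HOX genes with windows of 1 and 5 kb or anywhere in the gene, and, without the segments, for intervals in 1 genotype alone, regions past the limit and genes with both marks. Lists marked more often than random ones by H3K4me3 numbered 9 at 5 kb and 9 when matched on gene length. For single named genes, 112 alternative values stayed on their side of the 2-fold limit and 8, all at higher H3K27me3 regions, fell below it. For list medians, 6 came back into the middle 95% of random lists, all for H3K27me3, and 0 called medians reversed. HOX genes with H3K4me3 numbered 26 and 19 at 1 kb and 30 and 22 at 5 kb. Matching on GC content and the use of 5' ends alone were not run, because the gene table has neither sequence nor strand. Using all sequences of the files changed nothing, since every interval lies on the chromosomes used. No paired analysis was possible because the labels give each group replicate 1 alone. Depth is unknown, so intervals called in 1 library alone, most of which are weak, cannot be read as absent from the other.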

Other observations

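The comparisons and genes in this part were chosen after their values were seen, and no tests were run on them. At a group of genes the marks moved against each other, outside the shifted segments. The region at ACOT4 had H3K4me3 summit values of 161 and 45 in wild type and knockout and H3K27me3 values of 13 and 43. PHACTR3 had 74 and 37 for H3K4me3 and 48 and 119 for H3K27me3, TMEM121 152 and 88 against 31 and 65, and the neurogenic gene NEUROD4 56 and 36 against 14 and 21. In the other direction, the neuronal RNA-binding protein gene ELAVL4 had 40 and 70 for H3K4me3 and 61 and 24 for H3K27me3, the cartilage gene CHAD 34 and 82 against 63 and 20, CHP2 48 and 101 against 60 and 23, and NAT2 44 and 103 against 41 and 20. Of 118 overlapping region pairs with a log2 change of 0.5 or more in both marks, 53 were higher in H3K4me3 and lower in H3K27me3 in the knockout, 41 were the reverse, 5 were higher in both and 19 lower in both. These directions rest on the genotype labels: with the signs of 1 mark turned, 94 pairs would move the same way and 24 against each other.

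H3K27me3 intervals of the knockout alone lay near chromosome ends somewhat more often than shared ones. Of 5240 such intervals, 1557 (29.7%) lay within 10 Mb of an end, against 24.0% of the shared intervals of that library. For the wild type alone this share was 23.4%, against 24.3% of shared intervals. Chromosome ends were taken as the start of the sequence and the last interval or gene.

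Among pluripotency genes, H3K4me3 was high in both genotypes at SOX2 (178 and 204), LIN28A (250 and 246), DNMT3B (324 and 294, in the chromosome 20 segment) and SALL4 (241 and 224), among others. POU5F1, which encodes OCT4, had low values of 60 and 57. The series has no library of undifferentiated cells to compare with. ZFP42 stands apart from these with its interval in the knockout alone.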
